A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

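The series holds 8 two-channel arrays of total RNA from Halobacterium salinarum NRC-1. Per the labels' protocols, RNA was prepared with a column kit, checked by PCR for DNA and on a Bioanalyzer, and hybridised with a standard mid-log reference, the sample in Alexa 532 on 4 arrays and in Alexa 647 on 4. The design text describes 4 samples on dye-flipped duplicate arrays. Each sample was therefore counted once, as the mean of its 2 arrays after turning every ratio to sample over reference.

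The deposited spot files give a mean intensity and a background median intensity per spot for each dye at a high and a low scanner setting, up to 65535 and without background subtraction, per the file headers and the values. They also give a spot confidence in percent, per the file headers, which was below 100 almost only near the scanner limit and was read as a mark of saturation. The authors' series matrix holds 1 value per spot and array on a log10 scale. Set against the spot files, its values followed the log10 ratio of Alexa 532 to Alexa 647 with r between 0.760 and 0.929, once the spots had been put in the order of the array's physical rows, against 0.0127 to 0.269 in file order. The matrix medians were 0.0648 and 0.0223 for the high-oxygen light sample (Alexa 532 array, then Alexa 647 array), 0.0531 and 0.0800 for the high-oxygen dark sample, 0.0362 and 0.0583 for the low-oxygen light sample, and 0 and 0.0804 for the low-oxygen dark sample. The scale and direction were read from this comparison. How the authors centred and filtered these values is not given in the sources used here, nor are the image software and its settings. The values were not centred here, so the array medians enter the alternative that uses them.

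Gene names came from the platform annotation of the matrix probes, carried to the spot files through the same order. It lists 532 probes, all with 1 symbol and none with several, and 10220 of the 10752 spots are unnamed here. The 4 spots of a feature were averaged, giving 2688 features, 133 of them named. Names can be old, and no genome coordinates were used.

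The scans were merged after the files had been seen: the high scan was used, and saturated spots took the low scan's net signal times the median ratio of both scans over spots between 20000 and 45000. That factor was 6.13 to 11.5 for Alexa 532, and for Alexa 647 21.9 to 25.4 on 7 arrays and 71.5 on the Alexa 647 array of the high-oxygen dark sample. Background was corrected with limma's normexp at an offset of 50, and ratios were normalised within each array by global loess with a span of 0.3. A feature was above background in a channel when its mean net signal exceeded 2 times the root mean square of the negative net signals. By this measure 98 of the 133 named genes were measured in every condition in both channels. Precision is limited by the number of arrays and samples.

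Tests used limma 3.58.1 and statmod 1.5.0 in R 4.3.3, and figures Python 3.11.15 with matplotlib 3.10.9. An additive model of oxygen and light was fitted to the 4 samples, which leaves 1 residual degree of freedom per feature and a prior of 3.78. Its intercept is the mean against the reference. Features with a Benjamini-Hochberg adjusted p below 0.05 were called. With 1 sample per condition the interaction has no test, and the residual holds sample spread and interaction together. Before the data were examined, the design, the gene lists, the rule for named genes and most alternatives were fixed. The rule took, per comparison, up to 10 named genes on each side among those past the test with 1 sign at both levels of the other factor and in both dye orientations, filled up with genes of at least 2-fold, up to 4 members of each list, and a fixed set of genes. For light at each oxygen level it took 5 genes on each side. Of 22 planned lists 13 had named members, 6 had at least 5 and were tested, and 9 had none. Ribosomal and transposase genes were to be found by description too, which was not used here.

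Lists were tested against the other named genes with limma's camera at a preset correlation of 0.01, adjusted over the 6 lists. This was first run with the model refitted on the 133 named genes, and was changed to the statistics of the fit over all features, the form written in the plan, after values had been seen. The change moved the citric acid cycle list against the reference from an adjusted p of 0.0555 to 0.0392, the 1 list call that it moved. With 1 residual degree of freedom the estimated correlations ran from -0.2 to 1 and say little about these lists.

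Alternatives covered background correction, normalisation, spot summary, leaving out the dimmest features (the lowest share of 0.25 by intensity), the authors' log10 matrix values, single dye orientations, array-level fits, the eBayes prior, thresholds, list tests and leaving out each array or sample. Choices added after the data were seen were single scans, features above background on every array, leaving out both arrays of the higher array numbers, the array-number run as a block, and the list tests against all features and refitted on named genes. Features above background were refitted alone, and were also tested with the statistics of the fit over all features, adjusted over these features. The refit and the trend fit had infinite prior degrees of freedom, so that the spread of each feature had no weight in them. In the array-level fits the correlation between arrays of a sample came out at -0.677, -0.429 and -0.290. A negative value makes the standard errors of a mean over both orientations smaller, so those counts are on the liberal side.

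The fit was tested on simulated data with 2688 features, of which 100 changed at each size, in 20 runs. Of features changed by 1 log2 unit 89.7% were recovered for oxygen, 92.5% for light and 99.6% for the reference, and of those changed by 0.5 log2 units 17.2%, 30.0% and 94.2%. Oxygen and light were simulated alike, so their difference in recovery reflects the spread of the simulation and not power. Calls on unchanged features averaged 6.05, 12.45 and 10.7 per run in the same order. Simulated ratios were recovered from spots with r of at least 0.979 and a slope of at least 1.10, so ratios can come out stretched. The simulated spots lay mostly far above background and varied less than the real ones. This recovery therefore does not cover features near background. Of unchanged lists 6.5% had p below 0.05, with genes drawn independently, so this rate does not cover lists whose genes vary together. Probes without a symbol were left out of the gene lists.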

Results

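Transcript levels were measured in Halobacterium salinarum NRC-1, an extremely halophilic archaeon, in a strain lacking the genes ura3, phr1 and phr2. The ura3 gene, also called pyrF, encodes the last enzyme of uridylate synthesis and serves as a selection marker. The phr symbol stands for genes of the photolyase family. Photolyases repair ultraviolet damage in DNA with the energy of light. Whether phr1 and phr2 both encode an active one was not examined here. Cultures of 50 mL were grown to mid-log phase in rich medium in 125 mL flasks. They were kept in high oxygen, with shaking at 210 rpm, or in low oxygen, with shaking at 100 rpm in a stoppered flask, and each oxygen level was combined with light or dark. One RNA sample stood for each of the 4 conditions. Each sample was hybridised to 2 arrays with the dyes exchanged, against a standard mid-log NRC-1 reference, which gave 8 arrays. Each array carried 2688 features of 4 spots, of which 133 had a gene symbol in the annotation used here. Values are log2 ratios of sample to reference, averaged over both arrays of a sample, so that each comparison of oxygen or light set 2 samples against 2. Nothing in the labels gives separate cultures of one condition. The p-values and SE rest on what the additive model of oxygen and light leaves over. Sample spread and the interaction of both factors are joined in it, and spread between cultures of one condition was not measured.

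The signal differed between arrays. In the channel of the sample, 25.2% of the features lay above background on the array of the high-oxygen dark sample in Alexa 532 and 29.3% on that of the high-oxygen light sample, against 67.8% to 93.9% on the other arrays. Both of these arrays also had array numbers apart from the rest. Of the 133 named genes, 53 were above background in both channels on all 8 arrays, and 19 were below it in the sample channel on both arrays of at least 1 condition. Of the genes given values below, the reference was below background on both arrays of 1 condition for cysS, hemL, endA and htr18, and of 2 conditions for bat, radB and uvrA, so the sizes of their differences are uncertain. Over all features both arrays of one sample correlated with a median r of 0.051, arrays of different samples with 0.54 in one dye orientation and with 0.060 in opposite orientations. In the brighter 1344 features these were 0.352, 0.721 and 0.318. The median standard deviation of the 4 spots of a feature lay between 0.24 and 0.32 log2 units on each array.

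**Figure D1:**
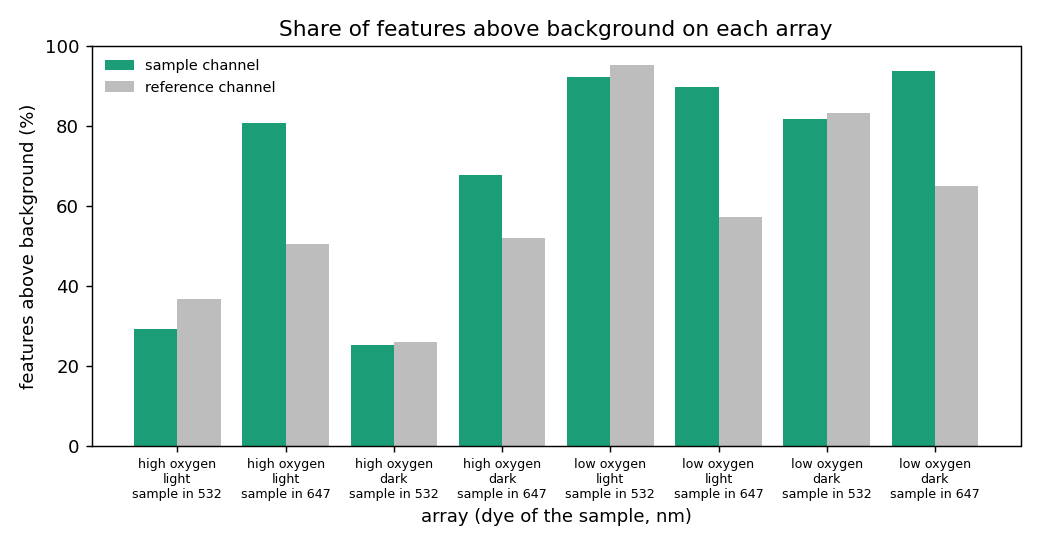
Share of features (percent, vertical axis) whose mean signal exceeded the background noise on each of the 8 arrays (horizontal axis, with the condition and the dye of the sample). Green bars are the channel of the sample and grey bars that of the reference. The sample channel reached 25.2% and 29.3% on the high-oxygen arrays with the sample in Alexa 532.

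Of the deleted genes, pyrF had a named feature, and phr1 and phr2 were not analysed here. The pyrF signal was not well above background on any of the 4 high-oxygen arrays in the sample channel, and it was above background on 3 of the 4 low-oxygen arrays. In low oxygen both channels were above background on 1 array of each sample, with log2 ratios to the reference of -0.60 with light and -0.92 in the dark, and the other array with light gave 0.16. Over all 4 samples limma gave -0.44 ± 0.08 (SE, n = 4 samples, adjusted p = 0.0264), a mean that includes the high-oxygen samples, where both channels were below background, and 1 such low-oxygen array, so its size is uncertain. Whether the feature lies in the deleted part is not given in the sources used here, and its level does not settle the labels.

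The first question was how transcript levels differed between low and high oxygen. Both named ribosomal protein genes, sucC and gdhA1 had higher values in low oxygen. The genes arcA, arcC and that of the ferritin-like protein DpsA had lower ones. However, no difference passed the test set before the data were examined. The ribosomal protein gene rpmC was 1.48-fold higher in low oxygen (log2 difference 0.57 ± 0.10, SE, 2 samples against 2), and rpl12p was 1.27-fold higher (0.35 ± 0.10). The succinate-CoA ligase gene sucC differed by 0.33 ± 0.10 and the glutamate dehydrogenase gene gdhA1 by 0.29 ± 0.10. On the lower side, dpsA, which binds iron and protects DNA, differed by -0.29 ± 0.11, and arcC and arcA, which encode carbamate kinase and arginine deiminase, both by -0.22 with SE 0.10 and 0.11. Each of these 7 genes had the same sign in light and in dark and in both dye orientations. So did 63 of the 133 named genes, so this agreement is common. Since no gene met the rule for naming set beforehand, gdhA1 here, and folP, speB and glnA below, were chosen after their values had been seen.

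In limma with the additive model of oxygen and light, 0 of the 2688 features passed an adjusted p of 0.05. The lowest adjusted p was 0.460, and 271 features had an unadjusted p below 0.05, where chance gives 134.4. Among the 133 named genes, 0 passed when adjusted over these alone, and no named gene reached a 2-fold difference. Both named ribosomal protein genes passed when adjusted over these 2 genes alone, with a lowest adjusted p of 0.00549. Across all other settings the count ran from 0 to 290, the highest by the authors' matrix values, with 74 higher and 216 lower in low oxygen. These values were not centred, and their array medians, turned to sample over reference, lay lower in low oxygen. A shift common to all features therefore enters this count and its balance. With a prior variance that follows intensity, whose prior degrees of freedom came out infinite against 3.78, 106 features passed, 74 higher and 32 lower, a balance opposite to that by the matrix. These held 11 named genes, 8 of them higher (rpmC, rpl12p, sucC, folP, gdhA1, speB, glnA and cbiG) and 3 lower (dpsA, arcA and arcC). Over the 620 features above background on every array, a choice made after the data were seen, 86 passed, 52 higher and 34 lower, and 68 of them were among the 106. That fit too had an infinite prior, so that all 620 features share a SE of 0.073 and the spread of each feature is left out. With the SE and prior of the fit over all features, 0 of the 620 passed. A fit with the array-number run as a block called 0 features, as did the Alexa 647 arrays alone, which lie in one run.

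Among the gene lists fixed before the data were examined, the flagella and chemotaxis list lay lower in low oxygen than the other named genes. Of its 11 measured members, which are transducer and signalling genes of taxis, 9 had negative and 2 positive differences, with a median of -0.07, and 0 passed singly (camera adjusted p = 0.00581). The adjusted p was 0.548 with an estimated correlation, 0.104 against all features, 0.0613 with the array-number run as a block and 0.0520 in the Alexa 647 arrays alone. Only htr6, cheB and htr18 were lower both in light and in dark. The genes htr4, htr7, cheR, cheY and cheA were higher in light and lower in dark, and htr8, htr1 and htr2 the reverse. The largest difference was that of the transducer gene htr18, -0.39 ± 0.11 (above background on 5 of 8 arrays in the sample channel and 3 of 8 in the reference channel). Further members gave -0.21 ± 0.16 (htr2) and -0.11 ± 0.10 (cheB), while htr4 was not well above background in either channel in high oxygen in the dark and gives no fold. No other list passed. Of all 133 named genes 84 had higher values in low oxygen, and counts of higher members are to be read against this share. The citric acid cycle list had 5 of 5 members higher in low oxygen with a median of 0.17 and 0 past the test (camera adjusted p = 0.248), with sucC, then citZ at 0.21 ± 0.12 and sucD at 0.17 ± 0.11. The cobalamin and heme list had 5 of 6 higher, with hemL at 0.23 ± 0.15, cbiG at 0.20 ± 0.10 and hemA at 0.19 ± 0.11, and none passed (camera adjusted p = 0.253). Purine and pyrimidine synthesis had 9 of 12 higher and none past the test (camera adjusted p = 0.402), led by purM at 0.27 ± 0.10 and purD at 0.25 ± 0.10.

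The rhodopsin and transducer list had 3 of 5 members higher and 2 lower, with a median of 0.01, while its test pointed down (camera adjusted p = 0.253). The values were -0.15 ± 0.11 for hop, the gene of the chloride pump halorhodopsin, and 0.05 ± 0.11 and 0.06 ± 0.15 for the sensory rhodopsin genes sop1 and sop2. The bat gene, which encodes the activator of the bacterioopsin gene, gave 0.22 ± 0.10, with the reference below background on 6 of the 8 arrays. The chaperone and proteasome list had 4 of 6 members higher with none past the test (camera adjusted p = 0.726), of which psmA, a proteasome subunit gene, gave 0.17 ± 0.10. The symbol panB in this list is also that of a pantothenate synthesis gene. The 4 DNA repair genes with a symbol included uvrB with 0.23 ± 0.16, uvrA with 0.18 ± 0.15 and radB with -0.10 ± 0.10, while mutL was not well above background in high oxygen. None passed. The respiratory genes sdhC and nuoL gave 0.07 ± 0.10 and -0.07 ± 0.10, msrA gave 0.09 ± 0.12 and phoU, the 1 named gene of phosphate uptake, 0.18 ± 0.16.

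**Figure D2:**
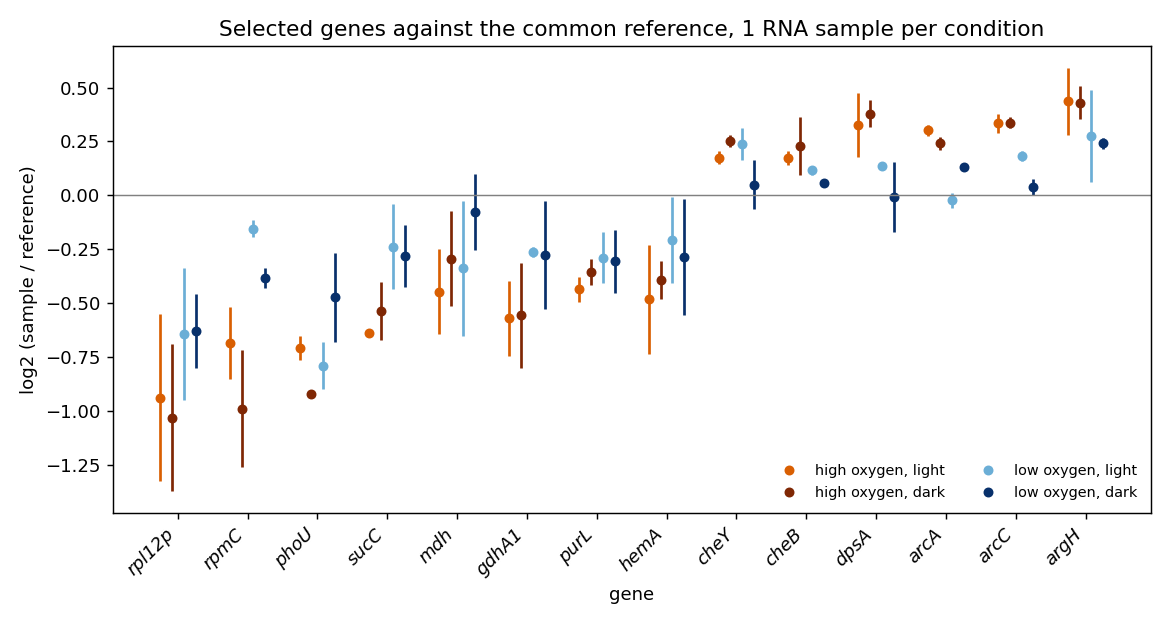
Log2 ratio of sample to reference (vertical axis) for 14 named genes (horizontal axis) in the 4 RNA samples, with high oxygen in orange and brown and low oxygen in blue. Points are the means of both arrays of a sample and lines run between its 2 dye orientations. For rpmC the low-oxygen samples lie at -0.16 and -0.38 and the high-oxygen samples at -0.68 and -0.99.

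The second question was how light and dark differed. Differences between light and dark were small, and none passed the test. The ribosomal protein gene rpmC was 1.20-fold higher in light (0.27 ± 0.10), and the phosphoserine phosphatase gene serB was 1.20-fold lower (-0.26 ± 0.10), each with the same sign at both oxygen levels and in both dye orientations. The cysteinyl-tRNA synthetase gene cysS, like serB named after its values had been seen, differed by -0.36 ± 0.10, bat by -0.30 ± 0.10 and sop2 by -0.27 ± 0.15. In limma, 0 of 2688 features passed an adjusted p of 0.05, the lowest adjusted p was 0.654, and 199 features had an unadjusted p below 0.05, where chance gives 134.4. Adjusted over the 133 named genes alone, 0 passed, and bat, the 1 named gene of its list, had an unadjusted p of 0.0330, with the reference above background on 2 of 8 arrays. With the intensity-dependent prior 2 features passed, and over the 620 features above background on every array 5 passed, of which serB and rpmC had symbols, both under an infinite prior. With the SE and prior of the fit over all features, 0 of the 620 passed. With the array-number run as a block, and in the 6 arrays of the lower run alone, the count was 0. The authors' matrix values gave 166, all of them higher in light. These values were not centred, and their array medians, turned to sample over reference, lay higher in light at both oxygen levels. A shift common to all features therefore enters this count, and its one direction is no evidence of a light response.

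No gene list passed the test between light and dark. Without the high-oxygen dark sample, flagella and chemotaxis (adjusted p = 0.00520) and the citric acid cycle (0.0156) passed. With all samples the lowest camera adjusted p was 0.804, for the citric acid cycle list, in which 4 of 5 members had lower values in light (median -0.10) and 0 passed, with mdh at -0.21 ± 0.10. Flagella and chemotaxis had 9 of 11 higher, with a median of 0.05 and 0 past the test (camera adjusted p = 0.820). Of all 133 named genes 61 had higher values in light. The DNA repair genes gave 0.16 ± 0.16 for uvrB and -0.14 ± 0.15 for uvrA, and the arginine fermentation genes 0.07 ± 0.10 for arcC and -0.05 ± 0.11 for arcA. Of the rhodopsin genes, hop gave 0.18 ± 0.11 and sop1 -0.14 ± 0.11. Tests on simulated data with the spread of these samples recovered 92.5% of the features changed by 1 log2 unit between light and dark and 30.0% of those changed by 0.5, over 2688 features. The oxygen runs, simulated alike, recovered 17.2% of those changed by 0.5, so power at that size is known only roughly.

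Whether light acted differently at each oxygen level rests on 1 sample against 1 sample, with no test. At high oxygen, 0 features differed at least 2-fold the same way in both dye orientations. At low oxygen, 2 were higher and 1 lower in light, and none of the 3 had a symbol. Across all 2688 features, which are not independent replicates, the light differences at high and at low oxygen correlated with r = 0.06, and with r = 0.15 in the brighter 1344 features. The oxygen differences in light and in dark correlated with r = 0.16 over all features and r = 0.40 in the brighter ones. Among the 65 named genes whose difference between both light effects had the same sign in both dye orientations, endA, a tRNA splicing endonuclease gene, stood highest. It gave -0.64 at high and 0.17 at low oxygen. The genes thiL, sop2, uvrA and hemL followed, with 0.49 to 0.52 for low minus high oxygen. The reference was above background on 5 of 8 arrays for endA and hemL and on 3 for uvrA. The tryptophan synthase gene trpB and the thymidylate kinase gene tmk stood lowest, but trpB was above background in the sample channel on 1 of 8 arrays and tmk was below it in both channels in high oxygen in the dark, so neither gives a fold. Beside them stood htr2 with -0.57, uvrB with -0.54 and phoU with -0.53. For htr2 and uvrB the difference came from the Alexa 532 arrays (-1.12 and -1.03) and was near 0 in the Alexa 647 arrays (-0.019 and -0.058). The median light effect of the citric acid cycle genes at low oxygen, -0.18 with 4 of 5 lower, lay at percentile 0.0200 of 10000 random lists of the same size and intensity. At high oxygen it was -0.02, at percentile 37.2. The other 5 lists lay between percentiles 8.45 and 94.0. Such a percentile takes the members as independent and leaves out the spread between cultures, so it is no test of light.

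The third comparison set the mean of the 4 samples of the deletion strain against the standard reference. Both named ribosomal protein genes and 3 of 5 named citric acid cycle genes fell below the reference past the test, and argH and arcC rose above it. The ribosomal protein genes rpl12p and rpmC fell by 0.81 ± 0.05 and 0.55 ± 0.05 on the log2 scale, phoU, a regulator of phosphate uptake, by 0.72 ± 0.08, and sucC and gdhA1 each by 0.42 ± 0.05 (SE, n = 4 samples, limma adjusted p between 0.0157 and 0.0168). Differences between the samples along oxygen and light are taken out of these SE, so they do not give the full spread of the 4 samples. Both arrays of a sample were averaged before the fit, so the difference between its dye orientations does not enter these SE directly. The purine synthesis gene purL fell by 0.35 ± 0.05, the heme synthesis gene hemA by 0.34 ± 0.05, thiL by 0.32 ± 0.08 and folP by 0.31 ± 0.06. The argininosuccinate lyase gene argH rose by 0.35 ± 0.05 and the carbamate kinase gene arcC by 0.22 ± 0.05. The other arginine fermentation gene, arcA, gave 0.16 ± 0.06 and did not pass, so 1 of 2 passed. The rule also named hutG, whose signal was not well above background in the sample channel on 6 of 8 arrays. The bat gene had a higher mean that passed the test, but a lower one by the Alexa 532 arrays alone, and its reference signal was above background on 2 of 8 arrays, so the size is uncertain. Calls on single genes were often lost: among the alternatives arcC passed in 15 of 33, sucD in 13 of 33, mdh in 19 of 33 and argH in 21 of 33, and rpmC in 24 and rpl12p in 26 of 33. The calls on thiL and folP passed in 14 and 18 of 32.

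In limma, 657 of the 2688 features passed, 342 higher and 315 lower than the reference, and 1142 had an unadjusted p below 0.05. Of the 657, 531 had one sign in all 4 samples and in both dye orientations, and the others did not. Among the named genes 32 passed, 4 higher and 28 lower, and 30 passed when adjusted over the 133 named genes alone. Past the test or not, 42 of the 133 had a mean above the reference, and counts of lower list members are to be read against this share. Of all features past the test, 4 reached 2-fold. The Alexa 647 arrays alone gave 642 and the Alexa 532 arrays alone 1. With the array-number run as a block 493 features passed, and 938 in the 6 arrays of the lower run alone. Without the Alexa 532 array the count was 1 for the high-oxygen light sample, 412 for the high-oxygen dark, 322 for the low-oxygen light and 1 for the low-oxygen dark sample, and without the Alexa 647 array it was 299, 44, 3 and 101 in the same order. The reference was measured on the same arrays, so its own spread is left out, and strain and growth conditions both differ from it.

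Among the lists, flagella and chemotaxis lay above the reference in 11 of 11 members with a median of 0.13, although 0 passed singly (camera adjusted p = 0.000179). Its adjusted p was 0.441 with an estimated correlation and 0.0286 against all features, and it passed under all 33 alternatives that changed the values or the fit. The values were 0.18 ± 0.06 for cheY, 0.17 ± 0.05 for htr6, 0.16 ± 0.05 for cheR and 0.14 ± 0.05 for cheB. The rhodopsin and transducer list was higher in 5 of 5 members, none of which passed, with a median of 0.08 (camera adjusted p = 0.0392). Its adjusted p was 0.441 with an estimated correlation and 0.218 against all features, with 0.339 under the array-number block, and it passed in 16 of 32 alternatives. Among its members sop1 gave 0.14 ± 0.05, hop 0.12 ± 0.05 and sop2 0.00 ± 0.07. Its members htr1 and htr2 also belong to the flagella and chemotaxis list, so these list results overlap. The citric acid cycle list was lower in 5 of 5 members, of which 3 fell (sucC, mdh by 0.29 ± 0.05 and sucD by 0.23 ± 0.06). Its camera adjusted p was 0.0392, and its adjusted p was 0.441 with an estimated correlation and 0.0224 against all features. Refitted on the named genes alone, which was the first form of the test that was run, the adjusted p was 0.0555. With the array-number run as a block it was 0.101, and the list passed in 17 of 32 alternatives. Purine and pyrimidine synthesis had 10 of 12 members lower, of which purL, carB, purM, purF and purD passed, and the list did not (camera adjusted p = 0.175), although it passed against all features (0.0286). The call on its member pyrF, the deleted gene, is no evidence on the pathway. Cobalamin and heme had 6 of 6 lower, of which hemA and cbiG passed (camera adjusted p = 0.175, and 0.0401 against all features). Of the chaperone and proteasome genes, 4 of 6 were lower and panB passed (camera adjusted p = 0.799). Of the remaining groups, 0 of 4 DNA repair genes, 0 of 2 oxidative stress genes and 0 of 2 respiratory genes passed, with dpsA at 0.21 ± 0.05. In the main fit dpsA passed only when adjusted over the 2 oxidative stress genes (limma adjusted p = 0.0261), and not over the 133 named genes (0.0511). Among the alternatives it passed in 10 of 33.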

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

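The test behind each weighed pattern was chosen after related results had been seen, and the genes listed here were picked out by the data.

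For 6 of the 10 genes named for the largest difference between both light effects, the light effect had one sign on both array pairs of high oxygen and the other sign on both pairs of low oxygen. The light effect at low minus high oxygen was -0.5433 for uvrB and -0.5283 for phoU. For trpB it was -1.016, but trpB was above background in the sample channel on 1 of 8 arrays, so neither sign nor size is secure. The light effect at low minus high oxygen was positive for the other genes. It was 0.4871 for hemL, 0.4886 for uvrA and 0.8064 for endA, whose sizes are uncertain, since the reference was above background on 5 of 8 arrays for hemL and endA and on 3 for uvrA. For uvrB and uvrA the opposite signs rest on the Alexa 532 arrays, since the light effect at high oxygen in the Alexa 647 arrays was near 0 (0.0078 and -0.038). These differences were not tested, since each condition had 1 sample. Of the 133 named genes, 22 behaved in this way, these 6 included, or 16.5%, where independent signs give 12.5%.

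The oxygen differences among the 620 features above background on every array were weighed first. A difference between both runs of array numbers as the whole cause is argued against by the Alexa 647 arrays, which lie in one run: their oxygen differences correlated with those of the Alexa 532 arrays with r = 0.381 (bootstrap interval 0.301 to 0.457). This holds for these features only. Taken in light and in dark separately, r between the dye orientations was 0.060 and 0.23 in the brighter features, and 0.087 and -0.24 over all features. Spread between single cultures stays open. On the Alexa 647 arrays the oxygen differences in light and in dark, which share no sample, correlated with r = 0.484 (0.405 to 0.553). With 1 sample per condition, culture differences that many features share can also give such an r. Its interval comes from resampling features and not cultures. Features are not independent replicates, and within the Alexa 647 arrays the high-oxygen samples have the lower array numbers, so array order stays open. Nor does r separate an oxygen response from a difference in ratio scale shared by the arrays of one oxygen level. The genes rpmC, rpl12p, sucC and gdhA1 were higher in low oxygen but lay below the reference, and dpsA, arcA and arcC the reverse. Their low-oxygen means thus lay nearer the reference than their high-oxygen means. A response to oxygen, to shaking or to the stoppered flask may also contribute, and these were not separated.

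The lower flagella and chemotaxis list in low oxygen was weighed next. The test of weak signal of its members did not decide. The list's median lay at percentile 4.82 of random lists matched on intensity, short of the bound set to argue against this, which is no support for it either. Of the 11 members, 7 were above background in both channels on every array. Among these cheR, cheY, cheA and cheB were lower in both dye orientations, while htr8, htr1 and htr2 changed sign between them. The difference between the runs of array numbers cannot be told apart from an oxygen response: in the Alexa 647 arrays the median was -0.109, below 0, but not beyond matched random lists (percentile 6.58). A response to oxygen stays open and untested.

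The low correlation between both arrays of one sample was weighed last, with r between -0.06 and 0.12 over all features. Signal near background may contribute, since in every sample r was higher in the brighter than in the dimmer features, by at least 0.350. A swapped dye label on 1 array, which would turn its sign, is argued against by the lowest r of 0.120 (bootstrap interval 0.0569 to 0.181) between arrays of opposite orientation in the brighter features. Arrays of one orientation from different samples correlated more closely (median r = 0.54 over all features) than both arrays of one sample (0.051), which correlated no more closely than arrays of different samples and orientations (0.060), so that part of each ratio follows the dye. A swapped sample label stays open, and no biological explanation was tested.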

How the results depend on the processing

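Most alternatives here were fixed before the data were examined. Those chosen after seeing the data are single scans, features above background on every array (refitted, or with the SE and prior of the fit over all features), leaving out both arrays of the higher array numbers, the array-number run as a block, and the list tests against all features and refitted on named genes. Keeping flagged spots was not run, since no flags are given for the spots, and the spot confidence was read as a mark of saturation only. Where a value moved, the cause was not tested, except for features above background on every array, and except that stricter or looser thresholds change counts by construction. Signal over background is one limit, beside 1 sample per condition: 620 of 2688 features were above it on all arrays. Named genes that were not past the test can also turn sign with the settings without being listed here, as bat did between light and dark in 3 of 32 settings and sop2 between low and high oxygen in 10 of 32. Low against high oxygen, rpmC (0.39 to 0.79), rpl12p (0.16 to 0.71), gdhA1 (0.17 to 0.50), dpsA (-0.40 to -0.044), arcA (-0.29 to -0.065) and arcC (-0.30 to -0.12) kept their sign in 33 of 33 settings and sucC (0.22 to 0.43) in 32 of 32.

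For oxygen, 82 features passed without background correction, 5 without the dimmest features, 290 by the authors' matrix values, 32 with 8 arrays and the sample as a random block, 106 with the eBayes trend, 2 in the low scan and 86 among features above background on every array. The named genes among them numbered 6, 1, 17, 1, 11, 0 and 10. Leaving out each array or sample gave 0 throughout for features and for named genes. The matrix calls were 74 higher and 216 lower, against 74 and 32 with the trend. The matrix values were not centred, so the shift of their array medians enters this balance, and also their counts for light and against the reference. The prior degrees of freedom, 3.78 over all features, were infinite with the trend and in the refit above background, 53.7 without background correction, and also larger by the matrix. A larger prior puts less weight on the spread of each feature. With the SE and prior of the fit over all features, 0 features above background passed for oxygen and 0 for light, so the 86 and 5 rest on the refitted prior.

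For light, 4 features passed without background correction, 166 by the authors' matrix values, 1 with 8 arrays and the sample as a random block, 2 with the eBayes trend and 5 among features above background on every array. The named genes numbered 4 by the matrix and 2 above background. Leaving out each array or sample gave 0 throughout.

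Against the reference, 657 features passed, and 1181 without background correction, 0 with plain subtraction (539 at an unadjusted p below 0.05), 387 with block-wise loess, 410 with scaling between arrays, 1200 by the authors' matrix values, 1 in the Alexa 532 arrays, 642 in the Alexa 647 arrays (405 of them among the 657), 1344 with 8 arrays and the sample as a random block, 1094 with the eBayes trend, 226 above background with the SE and prior of the fit over all features, 4 at 2-fold or more and 1053 at an adjusted p below 0.1. Of the matrix calls 73% were lower than the reference, and 58.2% without the dimmest features, against 47.9%. The median log2 ratio over all features was -0.0527 by the uncentred matrix values and -0.0097 in the main fit. The 32 named genes became 64 without background correction, 0 with plain subtraction, 17 with scaling, 60 without the dimmest features, 19 with the median of the spots, 66 by the matrix, 0 in the Alexa 532 arrays, 20 in the Alexa 647 arrays, 71 with the sample as a random block, 65 with the trend, 16 above background with the SE and prior of the fit over all features, 51 at an adjusted p below 0.1 and 0 at 2-fold or more.

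Leaving out 1 array or sample gave 0 to 412 features and 0 to 17 named genes against the reference. For the high-oxygen light, high-oxygen dark, low-oxygen light and low-oxygen dark samples in this order, the features numbered 1, 412, 322 and 1 without the Alexa 532 array, 299, 44, 3 and 101 without the Alexa 647 array, and 1, 0, 182 and 127 without the sample. The named genes numbered 0, 17, 13 and 0, then 12, 2, 0 and 4, then 0, 0, 9 and 4. A sample left out leaves 1 sample at a level, which is assumed to vary like the others.

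With the dye orientation as a replicate block, in which arrays share the replicate number and the dye of the sample, the fit called 0 features for oxygen, 1 for light and 1262 against the reference, with 64 named genes in the last. The numbers of list calls were the same with this block.

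Of the lists, 1 passed for oxygen. There were 2 by the matrix, 0 in the Alexa 532 arrays, 0 in the Alexa 647 arrays, 0 with the array-number run as a block, 0 among features above background, 3 without the arrays of the higher numbers, and 0 with an estimated correlation, with fry directional, with fry mixed and against all features. Leaving out 1 array or sample gave 0 to 3 lists: 3 without the Alexa 532 array and 0 without the Alexa 647 array of the high-oxygen light sample, 2 without the low-oxygen light sample and 0 without the low-oxygen dark sample. For light, with 0 lists, it gave 0 to 2, the latter without the high-oxygen dark sample. Against the reference, 3 lists passed, and 1 with plain subtraction, with block-wise loess, with the median of the spots, in the Alexa 532 arrays, with the array-number run as a block, in the high scan and among features above background. It was 0 with an estimated correlation and with fry directional or mixed, 4 against all features and 2 refitted on named genes. Leaving out 1 array or sample gave 1 to 3: it was 1 without the Alexa 647 array of each sample and without the high-oxygen light, high-oxygen dark or low-oxygen light sample. With the run as a block the adjusted p was 0.339 for rhodopsins and 0.101 for the citric acid cycle.

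For pyrF against the reference, the log2 ratio of -0.44 became -1.24 with plain subtraction, -0.37 with block-wise loess, -0.23 in the Alexa 532 arrays, -0.65 in the Alexa 647 arrays and -0.22 with the array-number run as a block, none of which passed. Leaving out 1 array or sample gave -0.55 to -0.33. The call was lost without the high-oxygen light Alexa 532 (-0.55), high-oxygen dark Alexa 647 (-0.34), low-oxygen light Alexa 532 (-0.35) or 647 (-0.54), and low-oxygen dark Alexa 532 (-0.53) or 647 (-0.35) array, and without the high-oxygen light (-0.39), high-oxygen dark (-0.49) or low-oxygen dark (-0.36) sample. Among values past the test in either setting, those that turned sign against the reference were mutL at 0.10 without background correction, hutG at -0.029 by the matrix and bat at -0.045 in the Alexa 532 arrays. Others turned sign without passing, such as uvrB in 15, sop2 in 12 and msrA in 6 of 32 settings, and nuoL in 9 and htr2 in 4 of 33. Of the calls named in the text, purM passed in 10 and carB in 11 of 32 alternatives and cbiG in 14 of 33. The median of the rhodopsin list was -0.050 in the Alexa 532 arrays. The r between the light effects at both oxygen levels, 0.06, became 0.17 with median centring, 0.20 without the dimmest features, 0.28 by the matrix, -0.042 in the Alexa 647 arrays and 0.19 among features above background.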

Other observations

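No test beyond the comparison with the reference was run for this part, and the probes named here were chosen after their values had been seen.

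The probes named here have no symbol in the annotation used here. They lay furthest from the reference on either side among such features that passed the test, had one sign in all 4 samples and in both dye orientations, and were above background in each channel on at least 4 of 8 arrays. Probe 4433 fell by 1.66 ± 0.06 (log2, SE, n = 4 samples) and probe 5161 by 1.09 ± 0.05, with limma adjusted p of 0.00494 and 0.00920. Probe 1605 rose by 1.02 ± 0.08 and probe 353 by 0.71 ± 0.07, both with limma adjusted p of 0.0157. The sample channel was above background on 6 of 8 arrays for probe 4433, 4 for probe 5161, 8 for probe 1605 and 6 for probe 353. The reference channel was above it on 6, 7, 8 and 6 in the same order.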
